A study of Homo sapiens with 6 samples.

How the data were processed

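RNA of K562, ImaR and PDR cells was compared on 6 two-colour arrays. Per the labels, total RNA of experiment 1 was labelled with Cy3 and that of experiment 2 with Cy5 on every array, so the dye and the experiment are 1 term and cannot be separated. Each of the 6 extracts was hybridised on 2 arrays. Each pair of lines was hybridised on 2 arrays with the dyes exchanged. The labels give all 6 arrays 1 common date, so no date batch could be tested.

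The deposited values are 1 log ratio per spot and array, taken here as log2, for 27648 spots with 0 missing values. The mean of every array was 0 to the precision of the table, and the array medians lay between -0.0143 and -0.0053. The scanner, the background correction, the normalization, the log base and the direction of the ratios are not given in the sources used here. Base 10 was left out as an option because the largest deposited value of 6.5 would exceed the range of a 16-bit scanner, which spans 4.82 on that scale. A natural logarithm stays possible. Single channel intensities were not used here, so signal over background is unknown. Spots numbered up to 9999 carry full precision and the other 17649 about 3 digits. The SD over spots of an array ranged from 0.287 for the array of K562 2 and ImaR 1 to 0.448 for that of PDR 2 and ImaR 1. The 321 spots of ACTB had an SD between 0.216 and 0.395 on an array. Their mean was 0.466 on the array of PDR 2 and ImaR 1, against 0.0477 to 0.241 on the others. The mean of the GAPDH spots on that array was 0.0027. That array also had the lowest quality weight, at 0.568 against 0.963 to 1.438, and every extract level draws on it.

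Of the spots, 17711 had 1 gene symbol in the platform annotation, 0 had several and 9937 had none. Symbols were updated with a table of RefSeq genes. In total 14718 spots were named through a RefSeq accession, 1808 through a current symbol and 1029 through an older one, and 156 kept the annotated name. Spots of 1 gene were averaged, which combined 2057 genes with more than 1 spot, and unnamed spots stood alone, for 24484 features in all.

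Each array was read as the level of its Cy5 extract minus that of its Cy3 extract. Per feature, the 6 extract levels were the minimum-norm least squares solution of the ring. limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over all features) was then fitted to these levels with line and experiment as terms, and a feature was called at an adjusted p under 0.05. Experiment numbers stand for the dye on every array, which is where the pairing comes from. The offset between the experiments had a median size of 0.105 and a mean square of 0.186, against 0.0928 for the closure of the ring. The extract test called 0 features for this offset, with 206 at an unadjusted p under 0.05, and generalised least squares 1.

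The direction of the ratios followed a rule fixed before the data were examined. Over features at least 2-fold from 1 on any array, the arrays of a pair of lines with exchanged dyes correlated at -0.362 for K562 and ImaR, -0.091 for K562 and PDR and -0.036 for ImaR and PDR. Over all features these values were -0.142, 0.037 and 0.037. The 32 relative sign patterns were ranked by the residual of the ring, and the common sign was taken from the 4 genes the study is known to have reported.

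Named genes were chosen by a rule fixed before the data were examined. For each comparison it took up to 10 named genes per direction with the largest change among those called with the same sign in both experiments, filled from genes over 2-fold in both experiments. It added FYN, AXL, CD44, HMGA2, LYN, BCR, ABL1 and ABCB1, and up to 4 members of each gene list with the largest mean change, with any called member. FN1, COL3A1, KRT19 and TIMP1 were chosen after their values were seen.

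The 27 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01, and an estimated correlation) and fry on the extract levels, adjusted over the lists. With an estimated correlation, both that estimate and the reference distribution of camera rest on 2 residual degrees of freedom. Chance levels for counts and correlations came from 100 simulations of unchanged lines, and for the overlap of calls from 20. A further 100 took the features of lowest p in each direction as lists of the observed sizes. All of these drew normal noise of the same size on every array for a feature. For features over 2-fold in both experiments, the chance level fixed beforehand was the count in opposite directions. The extract, array and generalised least squares fits were checked on data simulated for ImaR against K562 with 200 changed genes, and camera on 2 lists drawn from them, and fry was not checked.

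Windows of 40 genes that neighbour each other in the RefSeq table, without coordinates, were compared with 1000 shuffles of the genes, with each gene's change held within 0.5. In shuffled changes of PDR with 1 block of 40 genes raised by 0.2, a window passed in 18 of 20 simulations, against 1 of 20 with no block. For spot position, a running median over each spot and the 50 on either side was taken from every array, and spot gaps of the blocks were compared with 1000 random sets of 40 genes. Alternatives were a fit on the arrays, generalised least squares, no experiment block, median-centred arrays, arrays at a common spread, single spots, a filter on features under 0.2 on every array, robust eBayes, a 2-fold threshold, the common sign turned, natural logarithms and leaving out each array and each extract. Array quality weights were added after the data were seen. R 4.3.3 with limma 3.58.1 and MASS was used, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No genome sequence was used.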

Results

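Gene expression was measured in K562, a human chronic myeloid leukaemia cell line that carries the BCR-ABL fusion kinase, and in its derivatives ImaR, resistant to the ABL inhibitor imatinib, and PDR, resistant to the SRC and ABL inhibitor PD166326. Each line gave 2 RNA extracts, labelled experiments 1 and 2, and the 6 extracts were hybridised on 6 two-colour arrays of 27648 spots. Every array set an experiment 1 extract in Cy3 against an experiment 2 extract of another line in Cy5, and each extract was on 2 arrays, so that the arrays closed a ring. Each pair of lines was compared on 2 arrays with the dyes exchanged. After spots of the same gene were averaged, 24484 features were tested, of which 14547 were named genes and the rest unnamed spots. The labels do not say whether the 2 extracts of a line came from separate cultures, so p-values measure only the spread between these extracts and arrays. The number of arrays limits the precision of every value.

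The sources used here state neither the direction nor the log base of the deposited ratios. Differences are on the log2 scale on the assumption of base 2, and if the values were natural logarithms every fold would be larger. The direction, Cy5 over Cy3, is likely rather than stated. Of the 32 ways to turn the arrays against each other, the one with no array turned left the smallest residual around the ring, a mean square of 0.361 against 0.432 for the next. For the common sign, 3 of 4 genes that the study is known to have reported as higher in the resistant lines differed from K562 by at least 1 and all 3 pointed to this direction. These were CD44, HMGA2 and AXL, and the fourth was FYN. They were used to set the sign, so their rise is not independent evidence, and with the common sign turned every higher below would read lower.

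2 tests are given for each comparison. The moderated limma test on the 6 extract levels, fixed before the data were examined, had 2 residual degrees of freedom and a median standard error of 0.238 per difference between lines. Generalised least squares on the 6 arrays, an alternative also fixed before the data were examined, weighted extracts and arrays by their estimated variances and had a median standard error of 0.14. The variance between extracts was estimated at 0.0242 of that between arrays, over all features together. It comes from a ratio of 2 mean squares of the ring, expected at 1 where extracts add no variance. Over the 101 features that generalised least squares called in the mean of both lines this ratio was 0.979. Its 95% bootstrap interval over features was 0.624 to 1.632. For 125 features over 2-fold in either line it was 0.863 (0.609 to 1.16). A larger variance between extracts is therefore not excluded for the called features. In data simulated for ImaR against K562 over 24484 features with no variance between extracts, the extract test recovered 15 of 100 genes changed by 1 and all 100 changed by 2, with 0 false calls among 115. Generalised least squares recovered 97 and 100, with 18 false calls among 215. With equal variances of extracts and arrays, it recovered 13 and 97, with 19 false calls among 129. There the extract test recovered 1 and 65, with 3 false calls among 69, and a fit on the arrays 80 and 100, with 545 among 725. In both simulated settings the share of false calls by generalised least squares was over the 0.05 that the threshold aims at. Genes below are said to have risen or fallen only where a named test had an adjusted p under 0.05. Those that passed generalised least squares alone carry this higher error rate. Standard errors are those of the extract test, with n = 2 extracts per line.

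The first comparison asked how the imatinib-resistant line differed from its parent. In ImaR, CD44, a cell-surface receptor for hyaluronan, was 6.59-fold higher than in K562, with a log2 difference of 2.72 ± 0.236 (SE, n = 2 extracts per line). The matrix protein gene SPARC was higher by 2.55 ± 0.222, the gap junction gene GJA1 by 2.39 ± 0.274 and VIM, which encodes the intermediate filament protein vimentin, by 1.77 ± 0.254. The largest rise among the named genes was that of the mucin gene MUC19, at 3.44 ± 0.347. The epithelial adhesion gene EPCAM was lower by a log2 difference of -2.22 ± 0.254, which is 4.65-fold. These 6 genes rose or fell in the generalised least squares test, with adjusted p of 0.000693 for CD44, 0.0105 for SPARC, 0.002 for GJA1, 0.00262 for VIM, 0.00139 for MUC19 and 0.002 for EPCAM, and each had the same sign in both experiments.

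The other genes taken for ImaR also passed that test. TFPI2 and TFPI, which encode inhibitors of the tissue factor pathway of coagulation, rose by 2.52 ± 0.343 and 2.00 ± 0.228. NDRG1 rose by 1.97 ± 0.25, RNF113A by 1.78 ± 0.215 and HMGA2, which encodes a chromatin protein of embryonic tissue, by 1.78 ± 0.332. PIM1, a kinase gene that STAT5 activates, had a difference of -1.55 ± 0.212, and TNFRSF8, which encodes the receptor CD30, one of -1.68 ± 0.264. Their adjusted p lay between 0.00215 and 0.0109. For HMGA2 the 2 spots disagreed, at 3.30 and 0.26, whereas those of CD44, at 2.54 and 2.90, and of VIM, at 1.82 and 1.72, were alike.

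By generalised least squares 88 features differed between ImaR and K562, 64 higher and 24 lower, of which 52 and 19 were named genes. In the extract test 0 features passed, 347 had an unadjusted p under 0.05, and the smallest adjusted p was 0.076, for CD44 and SPARC. That test called 12 features, 11 of them higher, with the filter on flat features, and 10, 9 of them higher, at a common spread of the arrays. Without any test, 50 features were at least 2-fold apart in one direction in both experiments, 44 higher and 6 lower, against a mean of 0.57 and a maximum of 3 in 100 simulations of unchanged lines. Without either array of K562 and ImaR this count was 115, and at a common spread of the arrays 121. In opposite directions 92 features were 2-fold apart, and this count was the chance level fixed before the data were examined. The 50 did not exceed it. The experiments share arrays around the ring, so their errors oppose each other, with a simulated correlation of -0.501. Opposite directions were not counted in the simulations, which gave all arrays the same noise per feature. Neither level therefore settles how many of the 50 arose by chance. A fit on the arrays called 104 features, 0 without the first K562 or the second ImaR extract, 3 without the second K562 extract, and 10 to 72 without any 1 array or any of the other extracts.

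The second comparison set the PD166326-resistant line against K562. EPCAM was 19.2-fold lower in PDR, a log2 difference of -4.26 ± 0.254 (SE, n = 2 extracts per line), with -4.20 in experiment 1 and -4.33 in experiment 2. CD44 was 7.59-fold higher, a difference of 2.92 ± 0.236, with 3.19 and 2.66 in the 2 experiments. Both passed the extract test, with adjusted p of 0.0105 for EPCAM and 0.0446 for CD44. COL1A2, a chain of type I collagen, rose by 2.40 ± 0.228, 5.3-fold, in the generalised least squares test, with an adjusted p of 0.00092 there and 0.0934 in the extract test.

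HMGA2 rose by 2.13 ± 0.332 in PDR by generalised least squares, with its spots again apart at 4.15 and 0.12. By the same test the trypsinogen gene PRSS2 rose by 1.96 ± 0.248, NDRG1 by 1.87 ± 0.25, MYO3B by 1.70 ± 0.284 and the fatty acid receptor gene CD36 by 1.59 ± 0.298. PIM1 had a difference of -1.22 ± 0.212 and the phosphoinositide 3-kinase gene PIK3CD one of -1.16 ± 0.286, and both fell. Adjusted p for these 7 genes lay between 0.00352 and 0.0449. ATP9A at 2.48 ± 0.697, TMEM158 at 1.73 ± 0.49 and S100A16 at 1.65 ± 0.27 were over 2-fold higher in both experiments but passed neither test, with generalised least squares adjusted p of 0.0849, 0.0831 and 0.0606.

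By generalised least squares 52 features differed between PDR and K562, 43 higher and 9 lower, of which 34 and 6 were named genes. The extract test called only CD44 and EPCAM, with 341 features at an unadjusted p under 0.05. At least 2-fold in one direction in both experiments were 43 features, 38 higher and 5 lower, against a simulated mean of 0.48 and maximum of 3. In opposite directions 75 were so, the chance level fixed before the data were examined, which the 43 did not exceed. As for ImaR, the errors of the experiments oppose each other around the ring, which favours opposite directions. Neither level therefore settles how many of the 43 arose by chance. The extract call of CD44 was lost when any array or extract was left out, with adjusted p from 0.128 to 1, and at a common spread of the arrays, with 0.153, and that of EPCAM was lost in 11 of 12 such omissions. Over these 12 omissions the difference itself stayed between 2.66 and 3.17 for CD44 and between -4.43 and -4.00 for EPCAM. A fit on the arrays called 63 features, 0 without the first K562 or either PDR extract, 148 without the first ImaR extract, and 2 to 25 without any 1 array or either of the other extracts.

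**Figure D1:**
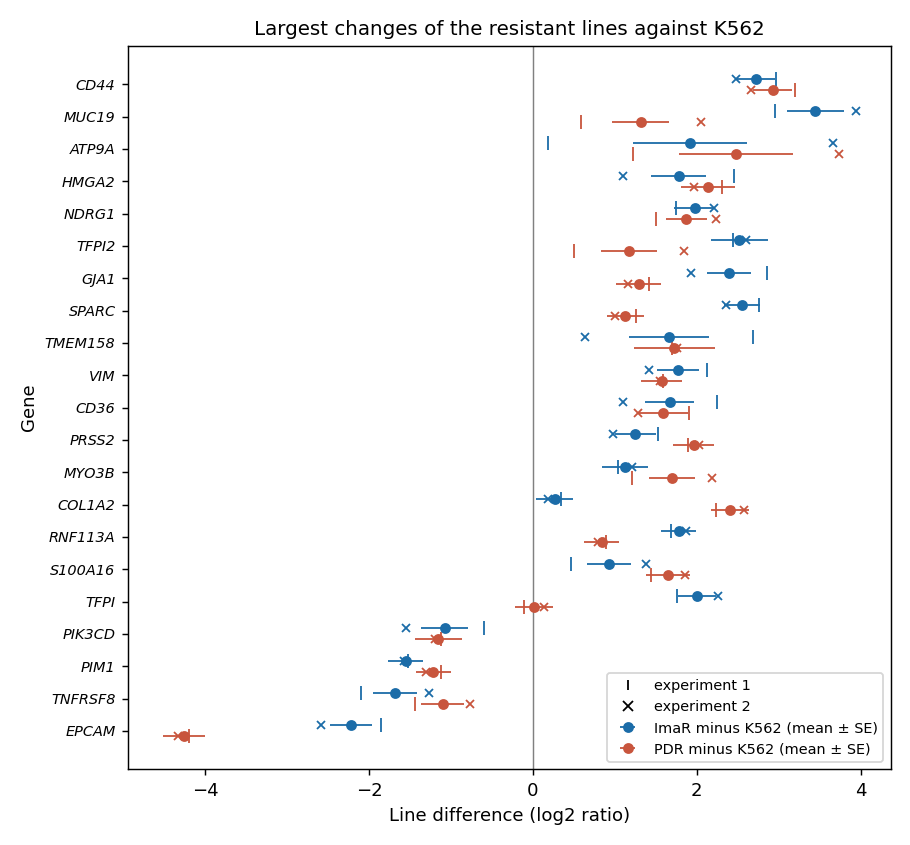
Log2 differences from K562 (horizontal axis) of the genes with the largest changes (vertical axis) in ImaR (blue) and PDR (red). Circles with bars are means ± SE of the extract test (n = 2 extracts per line), and ticks and crosses are experiments 1 and 2. CD44 was higher by 2.72 and 2.92 and EPCAM lower at -2.22 and -4.26 in ImaR and PDR.

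Taken as the mean of both resistant lines, CD44 was higher than in K562 by 2.82 ± 0.204 and EPCAM lower, at -3.24 ± 0.22, and both passed the extract test and generalised least squares. HMGA2 rose by 1.96 ± 0.288, NDRG1 by 1.92 ± 0.22, CD36 by 1.63 ± 0.26 and the receptor tyrosine kinase gene AXL by 1.51 ± 0.3 in the generalised least squares test. PIM1 fell, at -1.39 ± 0.18. That test called 101 features, 77 higher and 24 lower, against 2 in the extract test, where 370 had an unadjusted p under 0.05 and 0 passed once any array or extract was left out. A fit on the arrays called 106, 0 without the first K562 extract, 2 to 4 without the second K562, second ImaR or either PDR extract, 95 without the first ImaR extract, and 19 to 115 without any 1 array.

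Both lines were set against the same K562 extracts, which alone makes their changes resemble each other. Across features, the ImaR and PDR changes had a Pearson r of 0.492, against 0.5 (0.486 to 0.515) in 100 simulations of unchanged lines. Their covariance was 0.0231 against a simulated 0.0118, a difference of 0.0113. With ImaR from experiment 1 and PDR from experiment 2 the r was -0.270 against a simulated -0.249 (-0.268 to -0.231), and with the experiments exchanged -0.279 against -0.251 (-0.271 to -0.232), both below the simulated range. Without either array of ImaR and PDR the first r was 0.264, without the second PDR extract 0.323, and at a common spread of the arrays 0.656. The simulations in this paragraph gave every array the same noise per feature, while the SD of the arrays ranged from 0.287 to 0.448. Their ranges therefore hold only for arrays of equal spread, and no conclusion is drawn from them. Features are not independent replicates. By generalised least squares 24 features rose in both lines, of 64 in ImaR and 43 in PDR, against 0.112 for independent lists, and 5 fell in both, of 24 and 9, against 0.009. In 20 simulations of unchanged lines a mean of 0.05 features was called in both, but these lines had only 0.15 and 0.3 calls each, so this is no chance level for lists of the observed sizes. In 100 further simulations the features of lowest p, in lists of the observed sizes, shared a mean of 7.93 higher (at most 15) and 2.08 lower (at most 5). With 2 K562 extracts the controls were not split, so part of the overlap may come from them.

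**Figure D2:**
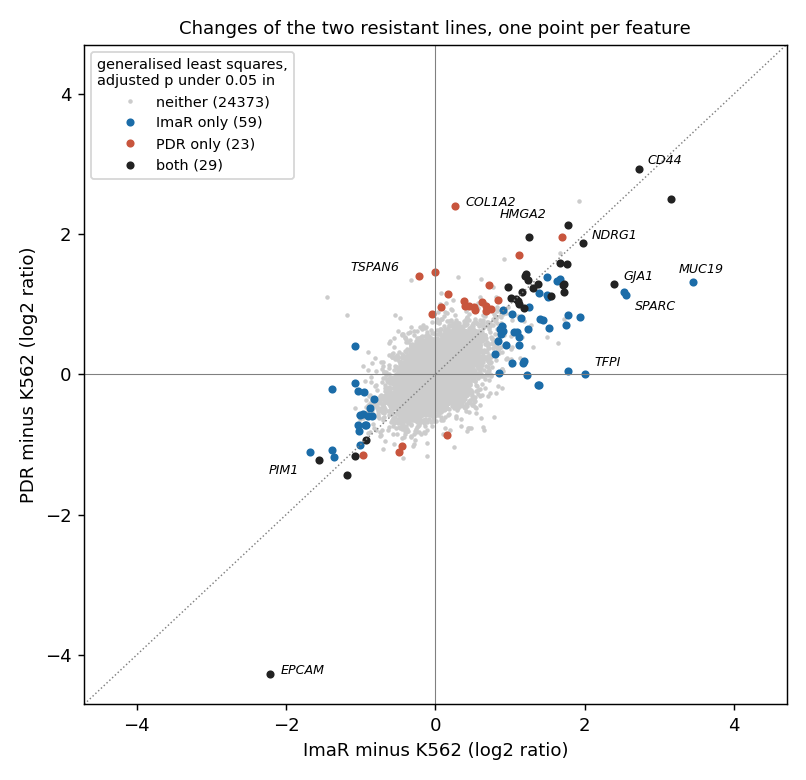
Log2 differences from K562 in ImaR (horizontal axis) and PDR (vertical axis), 1 point per feature, coloured by whether generalised least squares gave an adjusted p under 0.05 in ImaR only, in PDR only, in both or in neither. The dotted diagonal marks equal differences, and 29 features passed in both lines, including CD44 and EPCAM.

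Of 27 gene lists fixed before the data were examined, 11 moved apart from the other genes in the mean of both lines by camera with its preset correlation of 0.01. None passed with an estimated correlation, where the smallest adjusted p was 0.256, and none by fry in one direction, where it was 0.194. With an estimated correlation camera has only 2 residual degrees of freedom, so that a list could hardly pass. For STAT5 and JAK-STAT the estimate of -0.048 was below the preset, yet the unadjusted camera p went from 1.13e-07 to 0.0284. Not passing there therefore does not show that correlation between genes accounts for a list. With each spot taken on its own, 7 lists in place of 11 passed camera at the preset correlation. Values for lists are medians of the mean of both lines, and members that rose or fell are those of the generalised least squares test over all features.

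Genes of STAT5 and JAK-STAT signalling had a median of -0.145, with 16 of 21 measured members below 0, a camera adjusted p = 1.02e-06 and an adjusted p = 0.256 with an estimated correlation. PIM1 and SOCS1, a feedback inhibitor of JAK kinases, fell, SOCS1 at -0.73 ± 0.19, and the other 19 did not pass. STAT5A had differences of -0.85 ± 0.23 in ImaR and -0.37 ± 0.23 in PDR. Adjusted over the list alone, 5 members fell by generalised least squares and 1 by the extract test. The cholesterol synthesis genes had a median of -0.273, with 15 of 18 below 0, a camera adjusted p = 5.02e-07 and an adjusted p = 0.256 with an estimated correlation. EBP, a sterol isomerase gene, fell at -0.77 ± 0.19, and NSDHL fell in ImaR at -0.83 ± 0.21. Adjusted over the list alone, 7 members fell by generalised least squares and 0 by the extract test.

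Erythroid genes had a median of -0.214, with 18 of 25 below 0, a camera adjusted p = 0.0297 and an adjusted p = 0.364 with an estimated correlation. The delta-globin gene HBD fell at -0.74 ± 0.2, whereas ALAS2, which encodes the first enzyme of haem synthesis in red cells, stood at 0.68 ± 0.29 and did not pass. Adjusted over the list alone, 2 rose and 1 fell by generalised least squares and 0 changed by the extract test. The unfolded protein and amino acid stress genes had a median of -0.093, with 18 of 24 below 0, a camera adjusted p = 0.0169 and an adjusted p = 0.364 with an estimated correlation. None of them passed alone over all features, and SDF2L1 at -0.55 ± 0.25 and DDIT4 at -0.48 ± 0.19 were among the lowest. Adjusted over the list alone, 1 rose and 4 fell by generalised least squares and 0 changed by the extract test.

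Cell adhesion genes had a mean of 0.253 and a median of 0.03, with 16 of 29 above 0, a camera adjusted p = 0.000184 and an adjusted p = 0.364 with an estimated correlation. CD44, CD36 and the galectin gene LGALS1 rose, LGALS1 by 0.78 ± 0.21, and the other 26 did not pass. CD44 was among the genes used to set the sign, so the direction of this list is not independent of that choice. Adjusted over the list alone, 5 rose by generalised least squares and 2 by the extract test. The stromal and epithelial markers had a median of 0.059, a camera adjusted p = 0.0182 and an adjusted p = 0.498 with an estimated correlation. The smooth muscle actin gene ACTA2 rose by 1.48 ± 0.32, and COL1A2 and KRT19 also rose, while EPCAM fell. Adjusted over the list alone, 5 rose and 1 fell by generalised least squares, and 3 rose and 1 fell by the extract test. By fry's test of change in either direction the adjusted p of this list was 0.0273. The abundant stromal genes FN1 and COL3A1 stood at -0.19 ± 0.294 and 0.20 ± 0.199 and did not pass. Lymphoid markers had a median of 0.089, with 15 of 20 above 0, a camera adjusted p = 0.0153 and an adjusted p = 0.393 with an estimated correlation. CD3D, part of the T-cell receptor complex, rose by 1.00 ± 0.18 and was the only member called over the list alone, by either test.

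Oxidative phosphorylation genes had a median of 0.09, with 33 of 50 above 0, a camera adjusted p = 0.000653 and an adjusted p = 0.364 with an estimated correlation, and none passed over all features or, with 0 members by either test, adjusted over the list alone. Targets of p53 had a median of 0.085, with 12 of 16 above 0, a camera adjusted p = 0.00263 and an adjusted p = 0.364 with an estimated correlation. FDXR at 0.82 ± 0.23 and BTG2 at 0.70 ± 0.29 were the highest of them and did not pass over all features, and adjusted over the list alone 2 members rose by generalised least squares and 0 by the extract test. Glycolysis and hypoxia genes had a median of 0.114, with 18 of 30 above 0, a camera adjusted p = 0.0297 and an adjusted p = 0.498 with an estimated correlation. NDRG1 was the only member that rose, over all features and, by both tests, adjusted over the list alone, and LDHA stood at 0.40 ± 0.3. The list of 4 study genes, chosen by the study on these samples and so no independent evidence, had a camera adjusted p = 1.54e-19 and an adjusted p = 0.256 with an estimated correlation, and 4 members by generalised least squares and 3 by the extract test rose adjusted over the list alone.

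The other 16 lists did not pass camera. Their medians ranged from -0.045 for interferon response to 0.046 for apoptosis, with camera adjusted p of 0.79 and 0.139. The stem cell and self-renewal list, at an adjusted p of 0.0693, held HMGA2 and IGF2BP2, an RNA-binding protein gene that rose by 0.90 ± 0.23. Camera adjusted p was 0.865 for BCR-ABL and drug transport, for Src-family kinases and for heat shock, 0.903 for receptor tyrosine kinases, megakaryocytic genes, autophagy and lysosome and common reference genes, and 0.832 for myeloid genes. It was 0.419 for ERK feedback and early response and for the Wnt pathway, 0.337 for the cell cycle, 0.344 for cancer-testis antigens and 0.174 for ribosomal proteins. In those lists the protease gene CTSL rose by 0.77 ± 0.2 and PAGE1 fell at -0.72 ± 0.2. Adjusted over each list alone, each test called 1 receptor tyrosine kinase and 2 stem cell genes, all higher. These 2 lists hold AXL and HMGA2, which were used to set the sign. In the other 14 lists the extract test called 0 members. Generalised least squares called 1 lower among Src-family kinases, 1 higher and 1 lower in autophagy and lysosome, 1 higher and 3 lower among cancer-testis antigens and 1 higher among common reference genes. The mean and median differed in sign for Src-family and receptor tyrosine kinases. In ImaR and PDR alone 8 and 7 lists passed camera, and 0 with an estimated correlation.

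**Figure D3:**
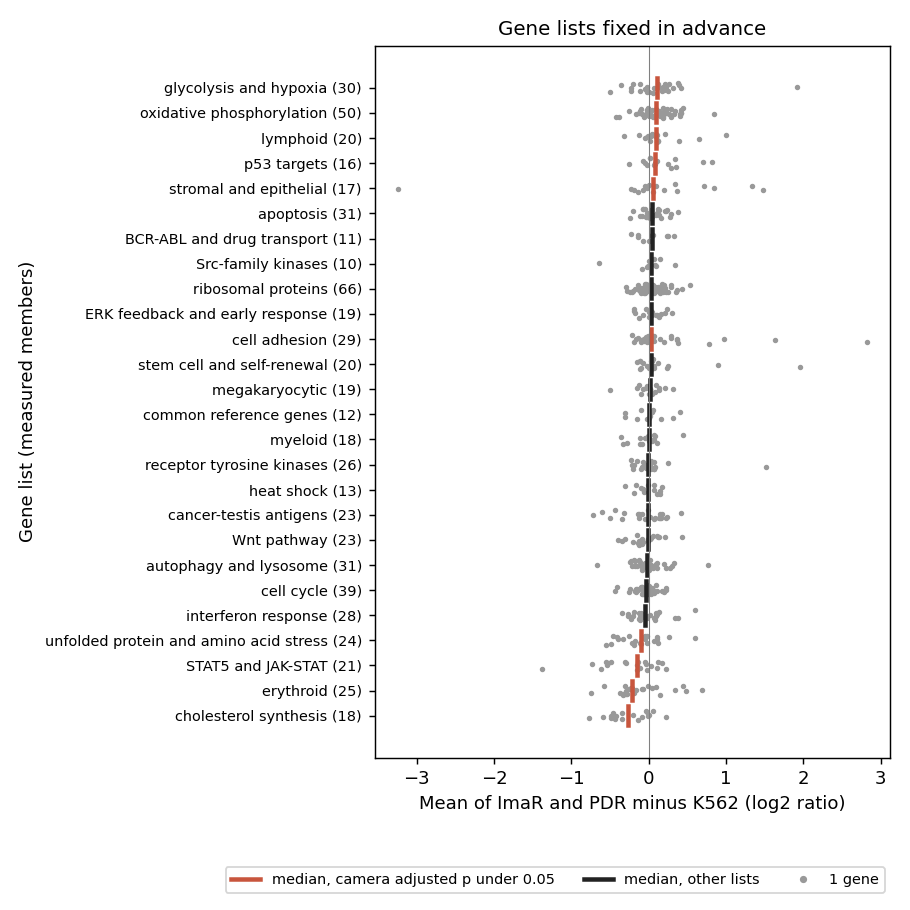
Mean log2 difference of ImaR and PDR from K562 (horizontal axis) for each measured member (grey points) of 26 gene lists (vertical axis, number of members in brackets), with the list median as a bar, red where camera gave an adjusted p under 0.05. The lowest medians were those of cholesterol synthesis, at -0.273, and erythroid genes, at -0.214. The list of study genes is left out.

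Of 8 genes fixed in advance, by generalised least squares CD44, HMGA2 and AXL rose in ImaR and CD44 and HMGA2 in PDR, and the other 5 passed neither test in either line. The SRC-family kinase gene FYN differed by 0.46 ± 0.232 in ImaR and 0.21 ± 0.232 in PDR, with generalised least squares adjusted p of 0.566 and 0.803, and its 2 spots gave 0.83 and 0.09 in ImaR. LYN stood at -0.68 ± 0.277 and -0.60 ± 0.277, with 0.218 and 0.326. AXL rose in ImaR by 1.67 ± 0.346, with 0.0183, and stood at 1.36 ± 0.346 in PDR, with 0.0571, while the difference between the lines had an adjusted p of 0.742. BCR differed by -0.05 ± 0.22 and 0.05 ± 0.22, ABL1 by 0.33 ± 0.26 and 0.15 ± 0.26, and the drug efflux gene ABCB1 by 0.24 ± 0.36 and 0.25 ± 0.36, and none of these passed.

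The last comparison set the 2 resistant lines against each other. COL1A2 was 4.41-fold lower in ImaR than in PDR, a difference of -2.14 ± 0.228 (SE, n = 2 extracts per line), and DLK1, which encodes a Delta-like membrane protein, was lower at -2.55 ± 0.406. TFPI was 3.98-fold higher in ImaR, by 1.99 ± 0.228, and EPCAM 4.12-fold higher, by 2.04 ± 0.254, since it fell further in PDR. MUC19 was higher by 2.13 ± 0.347. These 5 differences passed generalised least squares, with adjusted p of 0.00455, 0.0326, 0.00593, 0.00455 and 0.016 in that order.

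By the same test LAMB1, a laminin chain gene, was higher in ImaR by 1.39 ± 0.22. TSPAN6 at -1.62 ± 0.209, ROR2 at -1.49 ± 0.216 and the calcium-binding protein gene CALB1 at -1.47 ± 0.232 were lower, and 1 unnamed spot was higher by 1.72. Generalised least squares called 10 features, 5 in each direction. The extract test called 0, with 249 at an unadjusted p under 0.05 and a smallest adjusted p of 0.429. SPARC at 1.43 ± 0.222, PPARGC1A at 1.39 ± 0.917, DCTD at 1.28 ± 0.271 and SLC39A8 at 1.20 ± 0.279 were over 2-fold higher in both experiments without passing. SYNM at -2.03 ± 1.449, MAGEC1 at -1.39 ± 0.304, SLC41A3 at -1.28 ± 0.888 and VSIG4 at -1.06 ± 0.654 were lower in the same way. They were among 20 such features, 11 higher and 9 lower, against a simulated mean of 0.61 and maximum of 3. In opposite directions 43 were 2-fold apart, the chance level fixed before the data were examined, which the 20 did not exceed. Here too the errors of the experiments oppose each other, so neither level settles how many of the 20 arose by chance. Without either array of ImaR and PDR 36 features were 2-fold apart in one direction in both experiments. Without any other array or a K562 extract the count was 12 or 13. By camera 3 lists differed between the lines, the unfolded protein, heat shock and cholesterol synthesis genes, each with an adjusted p = 0.0281, and with an adjusted p = 0.782 with an estimated correlation. A fit on the arrays called 10, 0 without the array of ImaR 2 and PDR 1 or without the first K562, second ImaR or either PDR extract, and 4 to 14 with any other array or extract left out.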

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

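The tests of cell admixture, of another line and of the variance between extracts were chosen after the results were seen, and those of neighbouring genes and spot position before. ImaR and PDR differed in their change against K562 for 10 features by the generalised least squares test of the difference, and none of them passed the extract test. The differences of ImaR minus PDR were -2.55 for DLK1, -2.14 for COL1A2, 2.13 for MUC19, 2.04 for EPCAM, 1.99 for TFPI and 1.72 for an unnamed spot. They were -1.62 for TSPAN6, -1.49 for ROR2, -1.47 for CALB1 and 1.39 for LAMB1. Against K562, DLK1 stood at -1.45 in ImaR and 1.10 in PDR, and LAMB1 at 0.64 and -0.75, and neither line's own change passed. ROR2 fell in ImaR, at -1.08 with a generalised least squares adjusted p of 0.0373, and stood at 0.41 in PDR, with 0.578. These 3 genes pointed in opposite directions in the 2 lines. TFPI changed by 2.00 in ImaR and 0.01 in PDR, and COL1A2 by 0.26 and 2.40. Groups of 2 extracts were too small for a test of single extracts that stand apart.

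CD44, SPARC, VIM, TIMP1, GJA1, TFPI2 and HMGA2, grouped after their values were seen, rose in the mean of both lines by generalised least squares, with a median of 1.843. In PDR alone SPARC and TFPI2 passed neither test, with generalised least squares adjusted p of 0.275 and 0.0864, and the value of HMGA2 there rests on 1 of its 2 spots, at 4.15 and 0.12. Stromal cells mixed into the resistant cultures would bring their abundant collagen and matrix transcripts. The median change of the 7 measured abundant stromal genes was however -0.043 (95% bootstrap interval -0.142 to 0.36). It lay below 0.921, a cutoff derived from the median of the 7 grouped genes and assumed after the results were seen. The level that admixture would need was not measured. COL1A2 alone followed, and in PDR. Another cell line in full place of K562 would have lost the erythroid programme. The median of the 25 erythroid genes was however -0.214 (-0.287 to -0.013), well above -1. Another line making up only part of the cultures would lower these genes less, and the interval lay below 0. Such a partial admixture was not tested and stays possible. Spots too dim to respond could hide stromal cells or a full replacement, since intensities were not used. A change of the resistant cells themselves therefore stays a hypothesis.

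Line differences were shared by neighbouring genes. In PDR the 40 genes from NUDT6 to TMEM184C had a mean of 0.214, with 32 of 40 higher, and those from RPS6KA1 to FABP3 one of -0.183, each at a permutation p = 0.001, the smallest the 1000 shuffles can give. In ImaR the genes from PGRMC1 to RBMX2 had a mean of -0.159 (permutation p = 0.003), and the genes from GALM to FBXO11, which include EPCAM, were higher in ImaR than in PDR by 0.193, or 0.185 without EPCAM. Each had the same sign in both experiments. A running median along the spot order, taken from every array, lowered the largest window of 40 neighbouring spots. It went from 0.163 to 0.128 for ImaR and K562, from 0.164 to 0.139 for PDR and K562 and from 0.203 to 0.161 for ImaR and PDR, the last 2 still past their shuffled percentiles of 0.136 and 0.142. All 3 comparisons still had a window of neighbouring genes past the 95th percentile of the largest window in the shuffles. Neighbours in the 13 blocks, which can overlap between comparisons, lay a median of 6482 to 11126 spots apart, against 5282 to 11242 in 95% of random sets. Both argue against spot position, as far as spot numbers follow it and the running median removed its effect. The running median moved the gene differences by an SD of only 0.023 to 0.029, against their own SD of 0.228 to 0.234. Copy number differences between the lines may account for such blocks (0.214 in the largest), and base composition cannot be told apart from them because no sequence was used.

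The offset between the experiments, which cannot be separated from the dye, had a mean square of 0.186 against 0.0928 for the closure. Beyond this offset, the 2 extracts of a line differed no more than array noise. The ratio of the line-by-experiment to the closure mean square was 1.024 (0.999 to 1.049, 95% bootstrap over features). That ratio is expected to be 1 where extracts add no variance. Its interval comes from the features of 1 ring and does not measure the spread between extracts. The variance between extracts was estimated at 0.0242 of that between arrays. Data simulated with equal variances returned 1.017 for that estimate, so the ring can show such variance. Whether both extracts came from 1 culture cannot be told apart from cultures that hardly differ, because the labels do not say.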

How the results depend on the processing

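Array quality weights were chosen after the data were seen. The count of called features changed with how extracts and arrays were weighted and with which were left out. In the order ImaR and K562, PDR and K562, ImaR and PDR, and both lines and K562, the extract test called 0, 2, 0 and 2. A fit on the arrays called 104, 63, 10 and 106, generalised least squares 88, 52, 10 and 101, and array weights 165, 67, 10 and 144. Without the experiment block the extract test called 2 for ImaR, and the block changed no other count by over 1.5 times. Arrays at a common spread gave 10 (9 higher), 1 (lower), 0 and 9 (8 higher), with 121 features over 2-fold in both experiments for ImaR and an r of 0.656. Single spots gave 1 for ImaR and 1 for PDR, with 7 lists in place of 11. The filter on flat features gave 12 for ImaR and 6 for both lines, with fewer features tested. As natural logarithms the 2-fold counts were 123, 123 and 106. Leaving out single arrays or extracts, where a lone extract is assumed to vary like the others, gave 0 to 1 calls for PDR, 0 for both lines, 34 to 115 and 12 to 36 features over 2-fold for ImaR and for ImaR and PDR, and an r of 0.264 to 0.73. Fitted on the arrays, these omissions gave 0 to 72, 0 to 148, 0 to 14 and 0 to 115 calls. The causes were not tested. Of 7860 alternative values of 131 named genes, 7111 kept their side of the threshold and direction, 182 passed newly, 24 lost the call and 543 uncalled values changed sign, and no called value reversed. Over the 3 comparisons of 2 lines that these cover, only CD44 and EPCAM in PDR were called by the extract test, so the 24 losses are out of 40 alternative values, of which 16 kept the call. The other 7820 belong to values that were not called. A minimum of arrays per feature could not act, since no value was missing. Without intensities, signal over background limits the reading of small differences.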

Other observations

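Beyond the genes taken by rule, and chosen after their values were seen, TIMP1, COTL1, HEY1 and DPP4 rose in the mean of both lines by generalised least squares. TIMP1, an inhibitor of matrix metalloproteinases, differed by 1.70 ± 0.244 in ImaR and 1.28 ± 0.244 in PDR. The actin-binding gene COTL1 stood at 1.49 and 1.38, the Notch target HEY1 at 1.72 and 1.28, and DPP4, a surface peptidase, at 1.02 and 0.85. Among the genes that fell in the mean of both lines, RELN stood at -0.97 and -1.16 and the neuropeptide gene NMU at -1.01 and -1.01. Standard errors are those of the extract test, which none of these genes passed.

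Further blocks of 40 neighbouring genes lay past the 95th percentile of the largest window in 1000 shuffles. The comparison of ImaR and PDR is the difference of the other 2, and blocks of different comparisons can overlap. The blocks from GALM to FBXO11 and from RHOQ to TMEM17 both include EPCAM, for example. The 13 blocks are therefore not separate findings. In PDR these ran from UXT to PAGE1 at -0.163 (permutation p = 0.004), from MYCL to BEST4 at -0.158 (permutation p = 0.005), from TEX261 to LOXL3 at -0.152 (permutation p = 0.017) and from RHOQ to TMEM17 at -0.149 (permutation p = 0.023). The last of these includes EPCAM, and without it the mean of -0.14 is not past the percentile of 0.143. In ImaR they ran from PKD2 to BDH2 at 0.14 (permutation p = 0.024) and from SLC38A5 to NUDT11 at -0.139 (permutation p = 0.026). Between the lines they ran from PGRMC2 to PRSS48 at -0.213 and from MPHOSPH10 to POLE4 at 0.196, both at the smallest permutation p of 0.001, and from NAP1L5 to PPA2 at 0.146 (permutation p = 0.02).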
